A study of Mus musculus with 8 samples.

How the data were processed

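RNA from mouse ES cells (3 arrays), neural precursor cells (NPC, 3 arrays) and embryonic fibroblasts (MEF, 2 arrays) had been hybridised to whole-genome oligonucleotide arrays with 45101 probe sets. The deposited values were linear probe set intensity, 1 value per probe set and array. GCOS 1.4 is named in the submitters' processing notes, and its algorithm, background and scaling settings are not stated. No detection calls were used. The arrays had no visible common scaling: medians differed 1.65-fold between the highest and lowest array and 2% trimmed means 2.10-fold, above the limit of 1.5 that had been fixed before the data were examined for keeping the deposited scaling. The geometric mean of the spike controls differed 1.74-fold.

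After 64 control probe sets were left out, 45037 remained. Of these, 34945 were listed with a single gene, 932 with several and 9160 with none, and only those with a single gene entered the gene results. Each of the 18193 genes was read from its brightest probe set over the 8 arrays, and 9010 genes had more than 1 probe set. Values were transformed to log2(intensity + 16) and quantile normalized, so folds of dim genes are understated. Positions in the genome were not used.

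Groups were compared in R 4.3.3 with limma 3.58.1 in a single linear model of the 8 arrays with a variance trend, so that the 2 MEF arrays shared the estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The comparisons were NPC with ES, MEF with ES and MEF with NPC, and genes higher in a single group than in both others were counted. Overlaps of the comparisons that share the ES arrays were set against 100 simulations of unchanged groups.

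Gene lists were fixed before the data were examined: 35 lists with 664 members, of which 614 were measured. Members without a probe set of their own were not analysed here. The lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. The genes named for each comparison followed a rule written beforehand. It took the 5 highest and 5 lowest differences among called genes whose arrays did not overlap and a fixed set of markers. From each list with at least 3 called members it took up to 3 in each direction, and from the others all called members. Any member of the sex chromosome list could be named, and for genes highest in a group the 5 with the greatest smaller difference. Of the 258 genes so named, 30 rest on probe sets with shared sequence, by the suffixes _x_at and _s_at. The alternative that leaves out shared sequence also drops the suffix _a_at, so it reaches genes outside these 30. Of 267 called results with further probe sets, 229 had all of these on the same side and none had one opposite by 1 log2 unit or more.

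The procedure was tested on simulated data with the group sizes of this study. Each gene had a single pooled spread for all arrays, and genes were drawn independently. Differences of 1.5 log2 units were recovered in 98% of genes for NPC with ES, 92% for MEF with ES and 96% for MEF with NPC. Among 17993 unchanged genes, 0, 5 and 3 were called. A list shifted by 1 log2 unit in NPC was found (camera adjusted p = 6.85e-76) and 0 of 34 unchanged lists were called. With independent genes, this list result does not cover lists whose genes vary together.

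The alternatives chosen before the data were examined were median centring, pseudocounts of 1 and 64, leaving out the dimmest genes, the mean of a gene's probe sets, leaving out probe sets of shared sequence, a fit with no variance trend, array weights, a fit of the compared groups alone, the replicate number as a term, other thresholds and leaving out each array. The deposited scaling, scaling to a trimmed mean and the list tests without each array or under other scalings were chosen after seeing the data.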

Results

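Messenger RNA was measured with a mouse whole-genome oligonucleotide array in 3 cell types. ES cells (3 arrays) were of the V6.5 line, pluripotent cells derived from the mouse blastocyst, grown first on irradiated feeder fibroblasts and then passaged on gelatin without feeders. Neural precursor cells (NPC, 3 arrays) were differentiated from ES cells in culture and kept in FGF2 and EGF. Primary embryonic fibroblasts (MEF, 2 arrays) were the third cell type. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The median log2(intensity + 16) per array ran from 5.13 to 5.57 as deposited and the 2% trimmed mean of the intensity from 111 to 232, with both MEF arrays brightest. The number of arrays limits the precision of every difference below, and no measure of depth exists for this assay.

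The 8 arrays fell into their 3 groups. Over all probe sets, log2 values correlated at 0.986 to 0.989 between ES arrays, at 0.992 between the MEF arrays and at 0.858 to 0.872 between arrays of different groups. NPC 1 stood apart within its group, with correlations of 0.967 and 0.969 to NPC 2 and NPC 3, which correlated with each other at 0.987. The first principal component held 50.7% of the variance, the second 37.7% and the third 5.15%. The median SD of a gene was 0.135 log2 units among ES arrays, 0.211 among NPC arrays and 0.0733 among the MEF arrays.

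**Figure D1:**
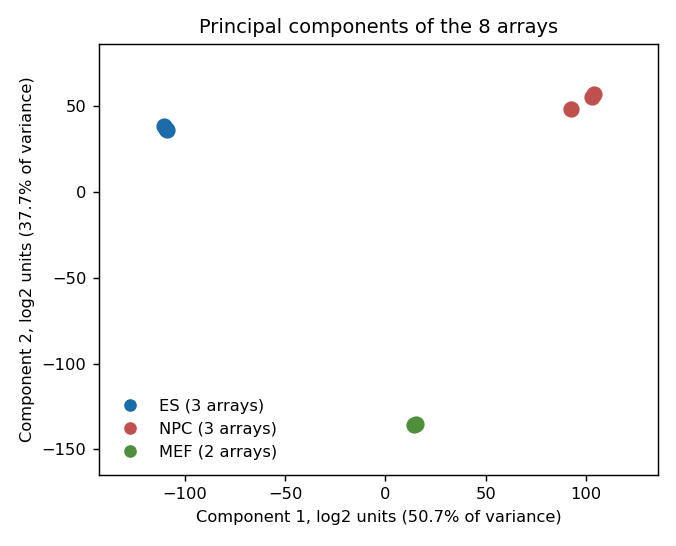
Each point is an array placed by its scores on the first 2 principal components of the log2 values, in log2 units, coloured by cell type. The first component (50.7% of the variance) separates ES from NPC arrays and the second (37.7%) separates MEF arrays from the rest.

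The comparison of NPC with ES cells asks which genes differ once pluripotent cells have taken a neural fate. Pou5f1, Nanog and Zfp42, which encode transcription factors of pluripotent cells, were near the bottom of the signal range in NPC. Pou5f1 was at 4.65 ± 0.21 (log2 intensity, SD, n = 3) in NPC and 12.01 ± 0.07 (n = 3) in ES cells, 164-fold lower, and Nanog was 180-fold lower and Zfp42 156-fold lower. Fabp7, a fatty acid binding protein of radial glia, was at 12.83 ± 0.31 against 4.22 ± 0.15 in ES cells, 389-fold higher. Nes, which encodes the intermediate filament nestin of neural precursors, was 15.9-fold higher, and Olig2, a transcription factor of the oligodendrocyte lineage, was 12.4-fold higher.

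The 5 genes with the largest falls from ES to NPC were Tdgf1, a co-receptor for Nodal, Dppa5a, Chchd10, Nanog and Pou5f1, with log2 differences of -8.61, -8.12, -7.84, -7.49 and -7.36. The 5 with the largest rises were Fabp7 (8.60), Ptn (7.67), a secreted growth factor, Gpm6b (7.20), Nfia (7.04), a transcription factor of gliogenesis, and Sparcl1 (7.01). Their standard errors lay between 0.092 and 0.22 and their arrays did not overlap between the groups. Pax6 rose by a log2 difference of 1.03 (limma adjusted p = 0.000319), close to the minimum of 1, and its call ended without NPC 1, at the deposited scaling (0.98 each), with a pseudocount of 64 (0.78) and with the mean of its probe sets (0.54). Sox2, which serves both pluripotent and neural precursor cells, stayed high in both groups, at 11.07 ± 0.48 in NPC and 12.05 ± 0.12 in ES cells. Its log2 difference of -0.98 did not reach the minimum, while it was -1.25 and called without NPC 1, and also passed without ES 3 (-1.04), with array weights (-1.24) and under the other scalings (-1.04 to -1.13).

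Among fixed gene lists, 29 of the 30 measured pluripotency genes were lower in NPC and Sox2 alone was not called (median log2 difference -5.52, camera adjusted p = 2.28e-21). Of 28 neural precursor genes, 22 were higher, with Fabp7, Ptprz1 (6.56) and Zic1 (5.57) leading, 5 were not called and Prom1 was lower at -2.28 (camera adjusted p = 2.34e-11). All 17 epithelial genes were lower (median -4.12, camera adjusted p = 2.8e-13), among them Cdh1, the epithelial cadherin, at -6.60, Epcam at -6.55 and Spint2 at -5.67. The mesenchymal list went the other way, with 6 of 13 higher and 2 lower (camera adjusted p = 0.0365, and adjusted p = 0.151 with an estimated correlation). Zeb1, a repressor of epithelial genes, rose by 4.28 and Vim by 3.29, while Fn1 fell by 3.81 and Mmp2 by 1.73.

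Of 20 germline genes, 13 were lower in NPC and none was higher (camera adjusted p = 1.17e-06), including Sycp3, of the synaptonemal complex, at -5.12 and Tex19.1 at -4.78. Of 11 genes for DNA methylation and its readers or erasers, 3 were lower and 2 higher. Dnmt3l fell by 5.51, Tet1 by 4.10 and the de novo methyltransferase Dnmt3b by 3.50, whereas the list as a whole did not pass (camera adjusted p = 0.759). Polycomb and Trithorax genes divided: 12 of 25 were lower and 3 higher (camera adjusted p = 0.0297, and adjusted p = 0.124 with an estimated correlation). Bmi1 was 13.6-fold higher and Phc2 6.34-fold higher in NPC, while the related Cbx7 was 27.4-fold lower and Phc1 8.03-fold lower.

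Cell cycle genes also differed. Of 23 proliferation genes, 11 were lower in NPC and none higher (camera adjusted p = 5.4e-06), with Ccnb2 at -3.29 and Bub1b at -1.92. Of 11 D cyclins and CDK inhibitors, 6 were higher and 1 lower (3 lower without NPC 1), and the list did not pass (camera adjusted p = 0.0522). Ccnd2 rose 28.1-fold, the CDK inhibitor Cdkn2c 12.9-fold and Ccnd1 8.1-fold, while Ccnd3 was 3.07-fold lower, a call that ended with the mean of its probe sets (-0.74). Its member Cdkn2a (chosen after its values were seen) was at 6.09 on NPC 1 against 8.60 and 8.72 on NPC 2 and NPC 3, while the list median on NPC 1 was 8.61. Cdkn2a was at 5.34 to 5.52 on the ES arrays and at 5.46 and 5.65 on the MEF arrays. The list passed with median centring (adjusted p = 0.0402), at the deposited scaling (adjusted p = 0.0297) and without ES 2 (adjusted p = 0.0473). Glycolysis genes were lower in 10 of 13 cases and none was higher (median -1.52, camera adjusted p = 6.38e-07), led by the glucose transporter gene Slc2a3 (-6.60), Pdk1 (-5.33) and Pfkp (-5.08). In the interferon and MHC class I list, 10 of 16 were lower and B2m alone was higher, at 1.94 (camera adjusted p = 0.000658). Ifitm1 fell by 7.23 and Bst2 by 5.29.

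Hox genes gave 4 higher and none lower of 33 (camera adjusted p = 0.316), with Hoxa5 at 3.39 and Hoxd8 at 2.76. Other developmental transcription factors were higher in 12 of 35 cases and lower in 1 (camera adjusted p = 0.00638, and adjusted p = 0.0819 with an estimated correlation), Lhx2 at 3.40 and Tbx15 at 2.69 against Gbx2 at -2.15. TGF-beta and BMP genes gave 9 lower and 2 higher of 17, and the list did not pass (camera adjusted p = 0.133). Ccn2 fell by 5.38 and Smad7, an inhibitor of the pathway, by 3.56, while the BMP target Id3 rose by 3.69.

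Markers of other lineages were mostly lower or not called in NPC. Of 20 neuron genes, 4 were higher, including Map2 (5.22) and Gap43 (3.92), and 5 lower, including Stmn2 (-7.04) and Nefl (-3.26), and the list did not pass (camera adjusted p = 0.465). Astrocyte genes gave 4 higher and 3 lower of 12 (camera adjusted p = 0.531), with Aldoc at 2.27 and Apoe at -5.75. Sparcl1 rose most in this list, at 11.02 to 11.26 on the NPC arrays against 4.10 to 4.16 on the ES arrays. Oligodendrocyte genes gave 1 higher, Cnp, and 3 lower of 12 (camera adjusted p = 0.71). Mesendoderm genes were lower in 6 of 15 cases (camera adjusted p = 0.0264, and adjusted p = 0.228 with an estimated correlation), a list call that also ended without NPC 1 (adjusted p = 0.0587), and trophoblast genes in 2 of 11, Tfap2c (-5.16) and Krt7 (-2.12; camera adjusted p = 0.223). Haematopoietic and macrophage genes gave 2 lower of 11 (camera adjusted p = 0.759), Cd68 at -3.31 and Laptm5, whose value of -3.70 became 0.74 without probe sets of shared sequence. Endothelial genes were lower in 3 of 10 cases (camera adjusted p = 0.229) and muscle, cartilage and fat genes in 4 of 12 (camera adjusted p = 0.103).

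Of 24 fibroblast genes measured, 9 were lower in NPC than in ES cells, 1 (Twist1, 1.83) was higher and 14 were not called (camera adjusted p = 0.113). Fn1 was at 11.68 ± 0.09 in ES cells and 7.87 ± 0.18 in NPC, and Lox, a collagen cross-linking enzyme, at 8.21 ± 0.21 and 4.62 ± 0.39. Contractile cytoskeleton genes were lower in 8 of 13 cases (camera adjusted p = 0.000658, and adjusted p = 0.0819 with an estimated correlation), with Tagln at -5.29. Acta2 (-4.33) and Tpm2 (-4.14) were also lower. Both calls ended when probe sets with the suffix _x_at, _s_at or _a_at were left out (-0.34 and -0.28). Tpm2 is not among the 30 named genes counted on probe sets with shared sequence. Extracellular matrix genes gave 12 lower and 4 higher of 25 (camera adjusted p = 0.042, and adjusted p = 0.185 with an estimated correlation), Lama1 at -5.11 and Timp1 at -4.53 against Tnc at 4.63 and Serpinh1, a collagen chaperone, at 2.37. That list call also ended without ES 3 (adjusted p = 0.0503) and without NPC 2 (adjusted p = 0.0667).

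Across all 18193 genes, 4173 differed between NPC and ES cells, 1828 higher and 2345 lower in NPC (limma, adjusted p under 0.05 and a log2 difference of at least 1). Among them, 649 were at least 4-fold higher and 860 at least 4-fold lower. Without NPC 1 the count was 4438, of which 3971 were among the 4173 with the same direction.

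**Figure D2:**
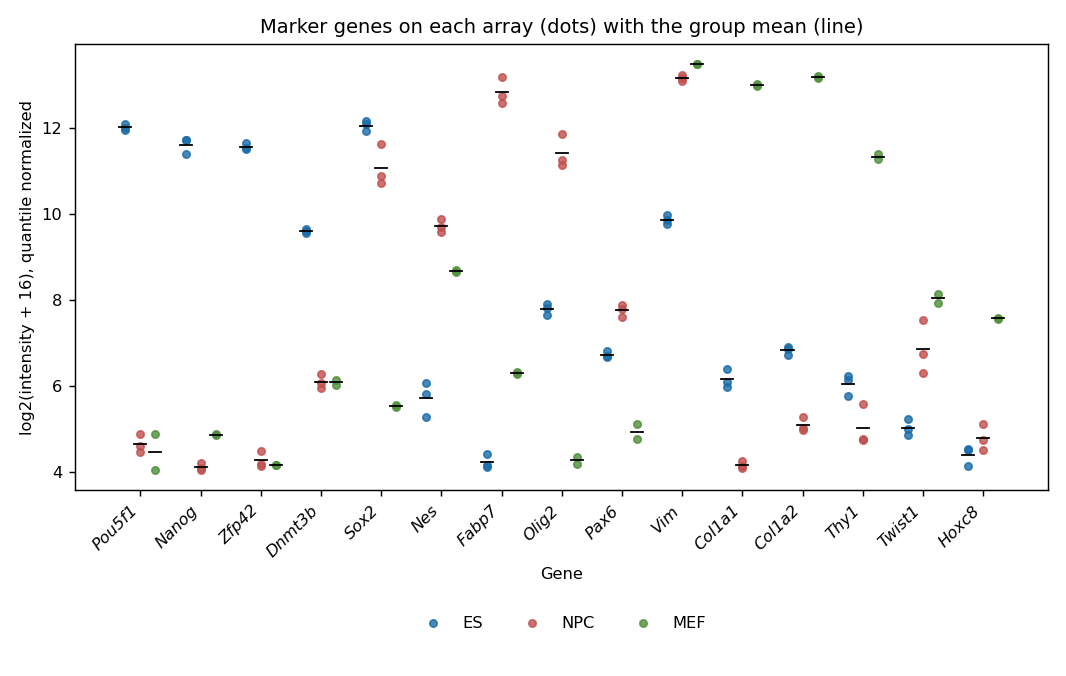
Dots give each array's log2(intensity + 16) after quantile normalization for 15 fixed marker genes, with black lines at the group means. Pou5f1, Nanog and Zfp42 are high on the 3 ES arrays alone, Fabp7 and Olig2 are highest on the 3 NPC arrays, and Col1a1, Col1a2 and Thy1 are highest on the 2 MEF arrays.

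The comparison of MEF with ES cells sets a somatic mesenchymal cell against the pluripotent one. Col1a1, which encodes the alpha chain of type I collagen, was at 12.99 ± 0.03 (log2 intensity, SD, n = 2) in MEF and 6.15 ± 0.21 (n = 3) in ES cells, 115-fold higher, and Col1a2 was 81.5-fold and Thy1, a fibroblast surface protein, 38.8-fold higher. The same factors were again near the floor: Pou5f1 was 186-fold, Nanog 107-fold and Zfp42 169-fold lower in MEF. Sox2, retained in NPC, was 91.2-fold lower in MEF, at 5.54 ± 0.03.

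The largest rises were those of Col3a1 (6.98), Col1a1 (6.85), Cdh11 (6.64), a mesenchymal cadherin, Postn (6.57) and Tm4sf1 (6.56). Tdgf1, Dppa5a, Pou5f1, Zfp42 and L1td1 had the largest falls, from -8.52 to -7.20. Twist1, a transcription factor of mesenchyme, was 8.06-fold higher and Dnmt3b 11.5-fold lower. Cdkn2a, a CDK inhibitor locus that is induced in cultured fibroblasts, was not called, at 5.56 ± 0.13 in MEF and 5.44 ± 0.09 in ES cells (limma adjusted p = 0.914).

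All 24 fibroblast genes were higher in MEF (median 5.18, camera adjusted p = 5.22e-17), as were all 13 contractile cytoskeleton genes (median 3.12, camera adjusted p = 3.88e-10) and all 13 mesenchymal genes (median 3.50, camera adjusted p = 3.88e-10). Actg2 rose by 5.87, Cnn1 by 4.80, Axl by 5.42 and Snai2 by 5.36. Of 25 extracellular matrix genes, 20 were higher and 3 lower (camera adjusted p = 2.56e-08), with Thbs2 and Tnc at 5.88 each and the laminin genes Lama1 (-3.63) and Lama5 (-1.66) on the lower side. TGF-beta and BMP genes were higher in 13 of 17 cases (camera adjusted p = 8.73e-08), led by Tgfb3 (5.67), Id3 (4.62) and Inhba (4.58). All 30 pluripotency genes were lower (median -5.72, camera adjusted p = 1.36e-21), and 15 of 17 epithelial genes were lower with Krt19 alone higher, at 1.67 (camera adjusted p = 1.59e-09).

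Hox genes, which set position along the body axis, were higher in MEF in 23 of 33 cases and lower in none (median 1.69, camera adjusted p = 4.27e-10). Hoxd13 rose by 4.15 and Hoxc8 by 3.18. Other developmental transcription factors were higher in 16 of 35 cases, including Foxc2 (4.07), Lhx9 (3.83) and Tbx15 (3.59), and lower in 3, Gbx2 (-3.16), En2 (-2.67) and Zic2 (-1.54, and -0.75 with a pseudocount of 64; camera adjusted p = 0.00113). The deposited scaling gave adjusted p = 0.0559 for that list. Germline genes were lower in 14 of 20 cases (camera adjusted p = 9.51e-08). Polycomb and Trithorax genes were lower in 13 of 25 cases and higher in 2 (camera adjusted p = 0.000692), with Cbx7 31.1-fold, Jarid2 15.9-fold and Phc1 14.5-fold lower against Bmi1 6.07-fold and Phc2 5.57-fold higher. The DNA methylation list did not pass (4 lower and 2 higher of 11, camera adjusted p = 0.0802), although Tet1 was 68.6-fold and Dnmt3l 26.8-fold lower.

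Of 23 proliferation genes, 14 were lower in MEF and none higher (camera adjusted p = 1.8e-07), with Bub1b at -1.64 and Mcm2 at -1.63, calls that ended under the deposited scaling (-0.83 and -0.84). D cyclins and CDK inhibitors were higher in 5 of 11 cases (camera adjusted p = 0.00896, and adjusted p = 0.0726 with an estimated correlation), among them Ccnd2 (4.89) and Cdkn2b (3.19). Glycolysis genes were lower in 5 of 13 cases, Slc2a3 by 4.84 on the log2 scale at most (camera adjusted p = 0.00896, and adjusted p = 0.108 with an estimated correlation). That list call ended with median centring (adjusted p = 0.156) and the deposited scaling (adjusted p = 0.153). Interferon and MHC class I genes gave 4 higher and 3 lower of 16 (camera adjusted p = 0.779), B2m at 2.92 and Ifitm1 at -4.61.

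Markers of blood cells were seen in MEF. Of 11 haematopoietic and macrophage genes, 7 were higher and 2 lower than in ES cells (camera adjusted p = 0.00625, and adjusted p = 0.065 with an estimated correlation), with Lyz2, the lysozyme gene of macrophages, at 3.98, Cd53 at 2.83 and Tyrobp at 2.82. Muscle, cartilage and fat genes were higher in 5 of 12 cases and lower in 1 (camera adjusted p = 0.00896, and adjusted p = 0.154 with an estimated correlation), including Col2a1 (2.60) and Actc1 (2.33). Neural precursor genes gave 12 higher and 6 lower of 28 (camera adjusted p = 0.101), Egfr at 3.73 and Vim at 3.61 against Olig1 at -5.20. Neuron genes gave 2 higher and 8 lower of 20 (camera adjusted p = 0.0562) and passed with median centring (adjusted p = 0.00719), at the deposited scaling (adjusted p = 0.000432) and without ES 3, NPC 3 or MEF 1 (adjusted p = 0.0402, 0.0441 and 0.039). The counts of higher and lower genes were, for astrocyte genes 1 and 3 of 12 (camera adjusted p = 0.448), oligodendrocyte genes 2 and 0 of 12 (camera adjusted p = 0.779), mesendoderm genes 1 and 4 of 15 (camera adjusted p = 0.281), trophoblast genes 2 and 1 of 11 (camera adjusted p = 0.993) and endothelial genes 2 and 2 of 10 (camera adjusted p = 0.979).

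In all, 4554 genes differed between MEF and ES cells, 2227 higher and 2327 lower in MEF (limma). The scaling set the balance of the 2 directions: 48.9% of the calls were higher in MEF with quantile normalization, 65.1% with median centring and 79.3% at the deposited scaling, where the median of all genes was shifted by 0.32 towards MEF.

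**Figure D3:**
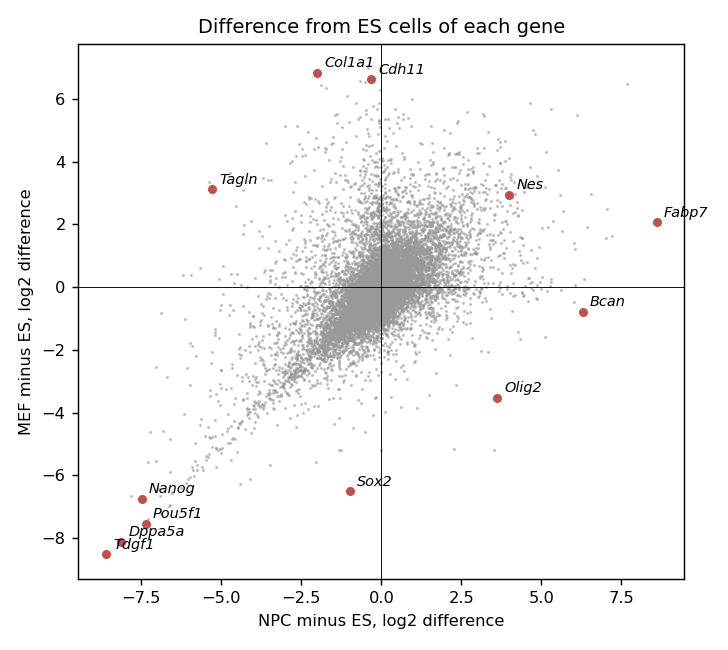
Each grey point is a gene, with its NPC minus ES log2 difference on the horizontal axis and its MEF minus ES log2 difference on the vertical axis. Pluripotency genes such as Tdgf1 (-8.61 and -8.52) lie at the lower left, Fabp7 (8.60) at the right and Col1a1 (6.85 in MEF minus ES) at the top.

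The comparison of MEF with NPC sets the lineage-restricted cell types against each other. Col1a1 was 459-fold, Col1a2 272-fold and Thy1 78.8-fold higher in MEF, while Olig2 was 142-fold, Fabp7 92.8-fold and Sox2 46.3-fold higher in NPC. Olig1, Aldoc, Olig2, Bcan, a brain proteoglycan, and Ncan had the largest falls from NPC to MEF, with log2 differences of -8.71, -7.45, -7.15, -7.07 and -6.71. The 5 largest rises were those of Col1a1 (8.84), the matricellular gene Ccn2 (8.73), Tagln (8.41), S100a6 (8.35) and Col5a2 (8.32). Vim was high in both, at 13.47 on each MEF array (n = 2) and 13.15 ± 0.07 in NPC (n = 3), a log2 difference of 0.32 that turned to -0.15 under the trimmed mean scaling.

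Nes was 2.05-fold lower in MEF (-1.03, limma adjusted p = 0.00359), a call that ended under median centring (-0.46), the deposited scaling (-0.11), the trimmed mean scaling (-0.99), the mean of probe sets (-0.64), a pseudocount of 64 and without NPC 2 (-0.95 each). Twist1 was 2.27-fold higher in MEF (limma adjusted p = 0.0163), and this call ended in the fit of the 2 groups alone and without NPC 3 (0.91), MEF 1 (1.27) or MEF 2 (1.07), and with a pseudocount of 64 (0.90). Hoxc8 was 6.89-fold higher in MEF.

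Neural precursor genes were lower in MEF in 19 of 28 cases and higher in none (median -1.46, camera adjusted p = 5.6e-08). All 24 fibroblast genes (median 5.19, camera adjusted p = 1.26e-19) and all 13 contractile genes (median 5.82, camera adjusted p = 1.3e-13) were higher, as were 23 of 25 extracellular matrix genes with Lama5 alone lower, at -1.52 and at -0.80 at the deposited scaling (camera adjusted p = 3.57e-14). Acta2, smooth muscle actin, rose 171-fold, Bgn 287-fold and the elastin and collagen cross-linking gene Lox 291-fold. TGF-beta and BMP genes were higher in 14 of 17 cases (camera adjusted p = 2.53e-10), with Ccn1 at 6.79 and Inhba at 6.15, and mesenchymal genes in 8 of 13, with Zeb1 alone lower at -2.01 (camera adjusted p = 2.68e-06).

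Hox genes went both ways: 19 of 33 were higher in MEF, including Hoxd13 (3.45) and Hoxb2 (3.39), and 3 were lower, Hoxa3, Hoxa4 (-1.69, and -0.84 with a pseudocount of 64) and Hoxa5 (-1.69; camera adjusted p = 2.68e-06). The Hoxa3 value of -1.53 rests on a probe set with shared sequence. Its brightest probe set without the suffix _x_at, _s_at or _a_at gave 0.54. The Hoxa5 call ended at the deposited scaling (-0.87). Other developmental transcription factors gave 4 higher and 5 lower of 35 (camera adjusted p = 0.362), with Foxc2 at 4.60 and En2 at -3.38.

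Glycolysis genes were higher in MEF than in NPC in 7 of 13 cases and lower in none (camera adjusted p = 5.6e-07), with Pfkp at 3.47 and Pdk1 at 2.91. Interferon and MHC class I genes were higher in 9 of 16 and lower in none (camera adjusted p = 5.05e-07), with Ifitm3 at 4.73, Ifi35 at 3.86 and H2-D1 at 3.48. Haematopoietic and macrophage genes were higher in 9 of 11 cases (camera adjusted p = 2.47e-06), Lyz2 at 4.19 and Cd53 at 2.73, and muscle, cartilage and fat genes in 9 of 12 (camera adjusted p = 6.66e-06). Epithelial genes were higher in 4 of 17, including Pkp2 (4.71) and Krt18 (2.38; camera adjusted p = 0.00126, and adjusted p = 0.157 with an estimated correlation), a list call that ended with median centring (adjusted p = 0.16) and the deposited scaling (adjusted p = 0.139). Polycomb and Trithorax genes gave 3 lower of 25 (camera adjusted p = 0.026, and adjusted p = 0.104 with an estimated correlation). That list call also ended with median centring (adjusted p = 0.81), with the deposited scaling (adjusted p = 0.913) and without NPC 1 (adjusted p = 0.0608). Tet1 was 4-fold lower in MEF and Tet2 3.04-fold, a Tet2 call that ended at the deposited scaling (-0.96), within a DNA methylation list that did not pass (3 lower of 11, camera adjusted p = 0.103).

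The pluripotency, germline and cell cycle lists did not pass between MEF and NPC. Pluripotency genes gave 3 higher and 2 lower of 30 (camera adjusted p = 0.906), Tbx3 at 2.75 and Sox2 at -5.53 among them. Germline genes gave 2 lower of 20, Stag3 (-2.85) and Prdm1 (-1.07; camera adjusted p = 0.277), and the Prdm1 call ended without NPC 1 (-0.63), without any single ES or MEF array, with median centring (-0.87), at the deposited scaling (-0.53), with a pseudocount of 64 (-0.71), with array weights (-0.72) and in the fit of the 2 groups alone. The germline list passed with median centring (adjusted p = 0.00248) and at the deposited scaling (adjusted p = 0.00585). Proliferation genes gave 2 higher of 23, Ccnb2 (1.51) and Ccne1 (1.28; camera adjusted p = 0.294), and the Ccnb2 call ended without MEF 1. D cyclins and CDK inhibitors gave 3 higher and 2 lower of 11 (camera adjusted p = 0.703), with 4 lower without NPC 1. Cdkn2b rose 17.9-fold (a log2 difference of 4.16 in MEF versus NPC, and 4.89 without NPC 1), and Ccnd1 was 3.4-fold lower, a call that ended at the deposited scaling (-0.91). Neuron genes gave 2 higher and 9 lower of 20 (camera adjusted p = 0.0676), astrocyte genes 2 and 5 of 12 (camera adjusted p = 0.124), oligodendrocyte genes 4 and 1 of 12 (camera adjusted p = 0.243), mesendoderm genes 3 and 1 of 15 (camera adjusted p = 0.333), trophoblast genes 4 and 0 of 11 (camera adjusted p = 0.139) and endothelial genes 3 and 0 of 10 (camera adjusted p = 0.102). The neuron list passed with median centring (adjusted p = 0.0014), at the deposited scaling (adjusted p = 4.74e-05), with the trimmed mean scaling (adjusted p = 0.0496) and without NPC 1 or NPC 2 (adjusted p = 0.0126 and 0.0457). The astrocyte list passed with median centring (adjusted p = 0.0463) and at the deposited scaling (adjusted p = 0.00491).

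Between MEF and NPC 3359 genes differed, 1912 higher and 1447 lower in MEF (limma). Higher genes made up 56.9% of the calls with quantile normalization, 74.1% with median centring and 87.5% at the deposited scaling, where the median of all genes was shifted by 0.43 towards MEF and 5095 genes were called.

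The camera test called 14 of the 35 lists in NPC versus ES, 17 in MEF versus ES and 14 in MEF versus NPC, and 7, 12 and 11 of these calls held with an estimated correlation. Adjusted over the list alone, the counts of higher and lower members equalled those over all genes in 102 of 105 cases, and the exceptions were p53 targets in both comparisons with ES cells and germline genes in MEF versus NPC. The median, mean and test of a list differed in sign in 16 cases. In NPC versus ES these were Hox, imprinted, ribosomal protein, haematopoietic and sex chromosome genes, in MEF versus ES astrocyte, oligodendrocyte, trophoblast, Notch, Hedgehog, interferon and endothelial genes, and in MEF versus NPC pluripotency, mesendoderm, D cyclin and Notch genes.

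Genes highest in a single cell type came from the same fit. In ES cells 1414 genes were higher than in both other groups, led by Tdgf1, Dppa5a, Pou5f1, Zfp42 and L1td1, whose smaller difference ran from 8.52 down to 6.90. NPC had 766 such genes, led by Fabp7 (6.54), Bcan (6.29), Gpm6a (6.08), the noncoding RNA gene Pantr1 and Kcnd3. MEF had 1132, led by Col3a1 (6.98), Col1a1, Cdh11, Postn and Tm4sf1. The MEF count rose to 1744 with median centring and 2721 at the deposited scaling, where the ES count fell to 903 and the NPC count to 461.

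Differences from ES cells overlapped between NPC and MEF. Of the 2345 genes lower in NPC and the 2327 lower in MEF, 1414 were shared, against 300 for independent lists of these sizes. Of the 1828 and 2227 higher genes, 855 were shared, against 224. In 100 simulations of unchanged groups set against the same ES arrays the shared number was 0 in both directions, a value that leaves out the differences themselves. The log2 differences correlated across genes at 0.55, and at 0.45 in the simulations, with covariances of 0.753 and 0.0181. These covariances argue against spread between the ES arrays as the main source of the correlation. With 3 ES arrays the controls could not be divided into separate sets of at least 2 arrays. Some part of the excess in shared genes may therefore still come from the shared ES arrays. In the opposite direction, 181 genes were lower in NPC and higher in MEF than in ES cells, and 52 were higher in NPC and lower in MEF.

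**Figure D4:**
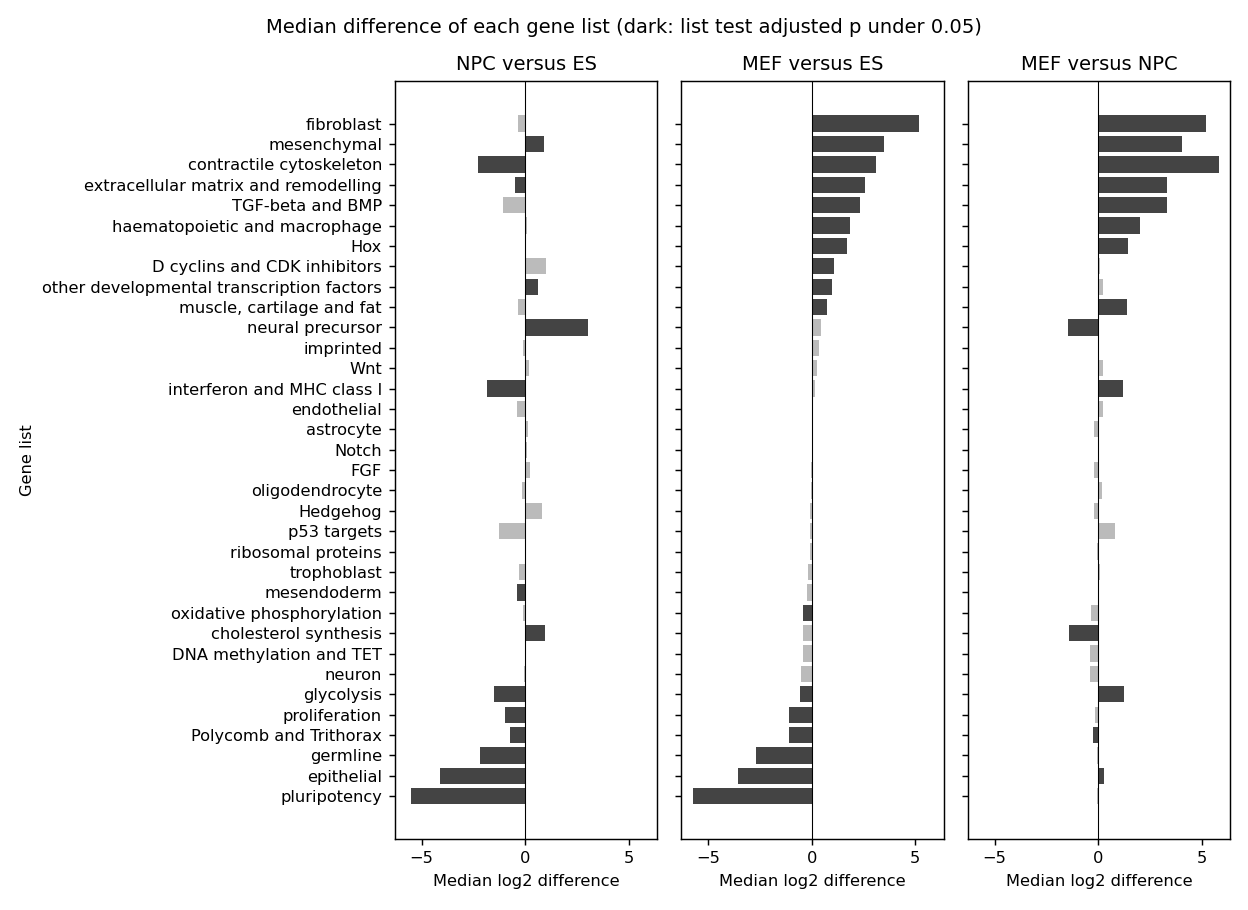
Bars give the median log2 difference of 34 fixed gene lists in each comparison, dark where the camera test passed at the preset correlation. The fibroblast list has its median at -0.33 in NPC minus ES, 5.18 in MEF minus ES and 5.19 in MEF minus NPC, and the pluripotency list at -5.52, -5.72 and -0.072.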

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

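The fit in this part was not listed among those planned before the data were examined, and no cause was tested. Probe sets that are listed with no gene or with several were outside the gene results, and 10092 of them were measured. A separate limma fit of these probe sets alone used the same thresholds, with adjustment over the 10092. It called 1012 between NPC and ES cells (668 higher and 344 lower in NPC). Between MEF and ES cells it called 935 (324 higher and 611 lower in MEF), and between MEF and NPC 1177 (267 higher and 910 lower in MEF). The gene fit called 4173, 4554 and 3359 of 18193 genes in these comparisons. The probe set fit was run with quantile normalization alone, so the balance of its directions under other scalings is not known. Among genes, 56.9% of the MEF versus NPC calls were higher with quantile normalization and 87.5% at the deposited scaling. They drew attention because they are signal in data that the gene comparisons do not use.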

How the results depend on the processing

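The deposited scaling, the trimmed mean scaling and the list tests without each array or under other scalings were chosen after seeing the data. Quantile normalization, listed beforehand as an alternative, became the reported setting, so it gave no separate values. Of 176 counts of genes under the alternatives, 147 lay within 1.5 times the reported count. The cause of the other shifts was not tested, apart from the thresholds and the pseudocount of 64, which by construction take more or fewer genes or shrink dim ones. Of 430 results of named genes, 280 kept their direction and their side of the threshold in every alternative run and 150 did not. Calls were lost with the sign kept 347 times over all runs. Of these, 123 came with the stricter thresholds and 57 with the pseudocount of 64, which lower the calls by construction. The mean of probe sets gave 38 and the deposited scaling 31, and leaving out a single array gave 2 to 13. Signal over background limits dim genes: the median log2(intensity + 16) of an array was 5.13 to 5.57, against 4 for an intensity of 0.

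With a pseudocount of 64, 2626 genes were called in NPC versus ES, 2937 in MEF versus ES and 2103 in MEF versus NPC. The count was 872 for genes highest in ES (the same set as those lower in both others), 495 for genes highest in NPC and 489 for genes higher than ES in both. With no minimum difference the counts were 8530, 8447, 7145, 3099, 1884 and 1979 in that order, and 2087 genes were highest in MEF. With an adjusted p under 0.01 and a log2 difference of at least 2 they were 1498, 1550, 1225, 442, 224 and 213, and 479 for MEF. At the deposited scaling 5095 genes were called in MEF versus NPC, 903 were highest in ES, 461 in NPC and 2721 in MEF, and median centring gave 1744 for MEF. With an estimated correlation 7 lists were called in NPC versus ES in place of 14.

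Without each array in turn, 4093 to 4438, 4392 to 4634 and 3096 to 3599 genes were called in the 3 comparisons, where a lone MEF array was assumed to vary like the other groups. The ranges were 1363 to 1439 for genes highest in ES, 675 to 881 in NPC, 1061 to 1151 in MEF and 796 to 906 for genes higher than ES in both. The list test called 13 to 15, 17 to 18 and 14 to 16 lists. Deviations of ES and NPC arrays of the same replicate number correlated across genes at -0.020 to -0.0021, and of other numbers at -0.026 to 0.040. These values gave no sign of pairing by replicate number, but 3 pairs cannot exclude it. Of the 10 splits of the 6 ES and NPC arrays into 3 and 3, the real split called 4173 genes and the highest of the others 0. Only 1 split reached the real count, but 10 splits are too few for a share under 0.05. Each other split mixed ES and NPC arrays on both sides, which widens the spread within a side. Its count of 0 is therefore not a count for unchanged groups, and no conclusion was drawn from it.

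Log2 differences that changed sign were few, and the cause was not tested. Without probe sets of the suffixes _x_at, _s_at and _a_at Laptm5 was 0.74 in NPC versus ES and 0.75 in MEF versus ES. Fabp4 was -0.079 in MEF versus ES and -0.014 in MEF versus NPC, and Hoxa10 -0.058 in MEF versus ES. Fabp4 and Hoxa10 are not among the 30 named genes counted on probe sets with shared sequence. In MEF versus NPC Hoxa3 was 0.54 and Plagl1 -0.046 in that setting. The trimmed mean scaling gave -0.048 for Cdkn2a in MEF versus ES and -0.15 for Vim in MEF versus NPC. The mean of probe sets gave 0.016 for Xist in MEF versus ES and -0.13 for Uty in MEF versus NPC. Eif2s3y, never called, was 0.30 with the mean of probe sets, 0.16 with array weights and -0.13 to 0.22 without single arrays in NPC versus ES. In MEF versus ES it was 0.45 with median centring, 0.77 at the deposited scaling and 0.36 with the mean of probe sets. In MEF versus NPC these were 0.53, 0.87 and 0.059, with 0.0086 for the replicate term and -0.27 to 0.075 without single arrays.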

Other observations

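The tests of the NPC arrays, of the scaling of macrophage genes and of feeder cells were chosen after the result was seen, while the second macrophage list was written before its values were seen.

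Imprinted genes, expressed from a single parental allele, differed widely without a common direction. In NPC versus ES 7 of 32 were higher and 8 lower (camera adjusted p = 0.933), with Meg3 at -6.12, Phlda2 at -6.53 and Nnat at 2.30. Some of these genes differed between the NPC arrays: on NPC 1 against NPC 2 and NPC 3, Mest was at 4.99 against 11.92 and 12.07 and Grb10 at 7.46 against 4.65 and 4.74 (genes chosen after their values were seen). In MEF versus ES 10 were higher and 4 lower (camera adjusted p = 0.356), and in MEF versus NPC 9 and 5 (camera adjusted p = 0.541), with the growth factor gene Igf2 at 4.96 and 7.26. Fgf4, a growth factor of pluripotent cells, fell by 6.26 in NPC and by 6.39 in MEF. The FGF list gave 7 higher and 3 lower of 19 in NPC versus ES (camera adjusted p = 0.316), 5 and 6 in MEF versus ES (camera adjusted p = 0.852) and 3 and 7 in MEF versus NPC (camera adjusted p = 0.161, and adjusted p = 0.0293 at the deposited scaling). Notch genes gave 4 and 4 of 16 (camera adjusted p = 0.459), 5 and 4 (camera adjusted p = 0.797) and 1 and 5 (camera adjusted p = 0.559), with Jag1 at 2.25 in NPC and 2.17 in MEF against ES cells. Wnt genes gave 6 and 4 of 18 (camera adjusted p = 0.325), 5 and 2 (camera adjusted p = 0.11) and 7 and 5 (camera adjusted p = 0.432), with the receptor gene Fzd1 at 4.07 in NPC versus ES. Hedgehog genes gave 5 and 2 of 10 (camera adjusted p = 0.243), 4 and 3 (camera adjusted p = 0.568) and 1 and 4 (camera adjusted p = 0.559), with Gas1 at 5.10 in NPC and 3.20 in MEF against ES cells.

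Cholesterol synthesis genes were higher in NPC than in ES cells in 5 of 12 cases (camera adjusted p = 0.00144, and adjusted p = 0.463 with an estimated correlation), including Cyp51 (1.93). NPC 1 stood apart, with a list median of 10.28 against 11.32 and 11.51 on NPC 2 and NPC 3 and 9.37 to 9.50 on the ES arrays, and without NPC 1 the higher genes numbered 9. Cholesterol synthesis genes were lower in MEF than in NPC in 10 of 12 (camera adjusted p = 0.000143, and adjusted p = 0.398 with an estimated correlation), including Dhcr7 (-2.63), and gave 1 higher and 2 lower in MEF versus ES (camera adjusted p = 0.448). No oxidative phosphorylation gene of 15 was called in any comparison. The list passed in MEF versus ES (median -0.40, camera adjusted p = 0.0119, and adjusted p = 0.0747 with an estimated correlation), but not with median centring (adjusted p = 0.733), and its direction turned at the deposited scaling (adjusted p = 0.881). It did not pass in NPC versus ES (camera adjusted p = 0.531) or MEF versus NPC (camera adjusted p = 0.0676, and 0.0379 with the trimmed mean scaling). Of 21 ribosomal protein genes Rps6 alone was higher in NPC than in ES cells (1.19, and 0.91 with the mean of probe sets; camera adjusted p = 0.759), none was called in MEF versus ES (camera adjusted p = 0.573) and Rpl14 alone was lower in MEF than in NPC (-1.02; camera adjusted p = 0.277). The Rpl14 call ended with median centring (-0.46), the deposited scaling (-0.12), the trimmed mean scaling (-0.98), a pseudocount of 64 (-0.90) and array weights (-0.99), and without NPC 2 or MEF 1 (-0.96 each). The trimmed mean scaling gave adjusted p = 0.00274 and 8.08e-05 for the ribosomal protein list in both MEF comparisons. Of 4 sex chromosome genes, 1 was lower in NPC versus ES (camera adjusted p = 0.933), 2 were higher in MEF versus ES (camera adjusted p = 0.382) and 2 in MEF versus NPC (camera adjusted p = 0.0798), the last passing with median centring (adjusted p = 0.0439) and without NPC 2 (adjusted p = 0.0454). Xist, lower in NPC versus ES at -2.39, was at -0.27 and not called without probe sets of shared sequence and at -0.86 with the mean of probe sets. In MEF versus NPC its call at 1.53 ended in these settings (0.26 and 0.88) and with a pseudocount of 64 (0.72). The Uty call in MEF versus ES, at 1.07, ended with a pseudocount of 64 (0.70), with the mean of probe sets (0.63) and without MEF 2 (0.96). The Y-linked gene Kdm5d was at 2.71 in MEF versus ES and 0.15, not called, in NPC versus ES.

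NPC 1 differed from NPC 2 and NPC 3 in targets of p53, the stress-response transcription factor. The list median was 9.26 on NPC 1, 8.98 to 9.23 on the ES arrays and 8.83 and 8.93 on the MEF arrays. On NPC 2 and NPC 3 it was 7.39 and 7.25, so these arrays lay below all others in the list median. The list gave 4 lower of 10 in NPC versus ES (7 lower adjusted over the list alone, camera adjusted p = 0.0763, and adjusted p = 0.559 with an estimated correlation), 3 lower in MEF versus ES (2 lower adjusted over the list alone, camera adjusted p = 0.617) and 3 higher in MEF versus NPC (camera adjusted p = 0.124, and adjusted p = 0.578 with an estimated correlation). Without NPC 1, 8 were lower in NPC versus ES (adjusted p = 5.83e-05) and 5 higher in MEF versus NPC (adjusted p = 4.95e-05), at the preset correlation. The NPC versus ES list test also passed with median centring (adjusted p = 0.0425) and at the deposited scaling (adjusted p = 0.043), with 7 lower in each. NPC 1 lay above both others in 9 of 10 targets, with the CDK inhibitor gene Cdkn1a (chosen after its values were seen) at 11.50 against 6.38 and 6.65. Cdkn1a was at 9.18 to 9.53 on the ES arrays and at 10.23 and 10.12 on the MEF arrays. The median SD of the list over the NPC arrays was 1.11, at percentile 100 of 10000 expression-matched random lists under each of 4 scalings. The list was picked for this spread, so the percentile gives no support of its own. Array brightness would move matched genes alike, and the median SD of the matched lists was 0.19, which argues against it. Of the other probe sets with a range of at least 1, 100% (6 of 6) shared the direction, which argues against a sequence variant. Leftover ES cells on NPC 1 are argued against by pluripotency genes, at a median of -5.40 on NPC 1 minus ES. Fibroblasts on NPC 1 are argued against by fibroblast genes, at a median of -5.86 on NPC 1 minus MEF. A difference in the state of the culture may stay as a candidate, for NPC 1 or for NPC 2 and NPC 3. No biological explanation was tested for it.

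Macrophage genes were higher in MEF than in NPC, Lyz2 by 4.19 and Cd53 by 2.73. A second list of 20 macrophage genes, none shared with the first or held by any other list, had a median MEF minus NPC difference of 1.28, at percentile 100 of expression-matched random lists, with 12 higher and 0 lower (limma). The first list had a lowest percentile of 99.99 over 4 scalings, but it was picked for this difference, so the percentile gives no support of its own. Array brightness would move matched genes alike. The matched lists had a median difference of -0.035 with the trimmed mean scaling and 0.42 at the deposited scaling. The first list was at 2.00 and 2.61 there, which argues against brightness. A candidate explanation is macrophages in the MEF cultures, for which the labels name no sort, and expression of these genes by fibroblasts themselves was not tested.

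Of the fibroblast genes, 9 were higher in ES cells than in NPC, and the ES cells had been grown on feeder fibroblasts. Feeders that resemble the MEF arrays would bring all abundant MEF transcripts, and Col3a1, at 0.544% of its MEF level in ES cells, sets the largest share they could hold. All 9 genes needed more, from 0.659% for Col1a1, 1.30% for Thy1 and 1.68% for Pdgfrb to 40.0% for Fn1. For the 5 genes that needed over 3 times that share, from Pdgfrb to Fn1, these values argue against feeders that resemble the MEF arrays. For the other 4, among them Col1a1 and Thy1, feeder RNA and expression by ES cells were not told apart. The feeders themselves were not measured and may differ from the MEF arrays, which limits both statements.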
